A study of Mus musculus with 2 samples.

How the data were processed

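Gene expression was measured on 2 mouse whole-genome oligonucleotide arrays hybridised with 1 Cy3-labelled sample each. The samples were beta cells of C57BL/6J mice aged 6 months on a high-fat diet. One sample came from wild-type animals (CSE-WT) and the other from animals lacking CSE (CSE-KO), with 1 array per genotype. CSE is cystathionine gamma-lyase, an enzyme of transsulfuration that produces hydrogen sulfide and is encoded by Cth. The labels named the wild type as the control, and differences are given as CSE-KO minus CSE-WT. How many animals gave each sample is not given in the sources used here.

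Per the labels' protocols, total RNA was extracted with TRIzol and column-purified, then amplified and labelled with a low-input Agilent kit. Per the file headers, each array was scanned and quantified with Agilent Feature Extraction 10.7.1.1, which gave a spatially detrended fluorescence intensity for each spot with no local background subtraction. The submitters' processing notes name version 9.5.1.1 of the same program. The authors also deposited a table of 55681 probe intensities on a linear scale. Each of its columns correlated with the log2 processed signal of its own array (Pearson r = 0.9999 across probes, which are not independent replicates). The correlation with the other array was 0.986 and 0.985. Both columns had a median intensity of 37.7, and their sorted values differed by at most 0.813 units, which is what quantile normalization gives. No centring was seen, and the exact steps behind the table stay unknown. Both arrays lay on 1 slide and came from 1 scan, so slide and scan did not differ between the genotypes.

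Each array held 62976 spots, of which 59305 were gene spots representing 55681 probes. A set of 399 probes was printed 10 times. Spots flagged as outliers were left out (139 of the gene spots on the CSE-WT array and 169 on the CSE-KO array), and no spot was saturated. The log2 of the processed intensity was taken, spots of 1 probe were averaged, and the 75th percentile over gene probes was subtracted on each array. That percentile was 519 intensity units on the CSE-WT array and 540 on the CSE-KO array. A probe counted as measured when it was well above background on both arrays, by the flag in the files. On the CSE-WT array 31716 probes (57.0%) were above background, and on the CSE-KO array 33177 (59.6%). The value of a gene was that of its measured probe with the highest mean level.

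Probe names came from the array files. Accessions were looked up in a table of current mouse gene names, which renamed or kept 27235 probes by accession, 3581 by symbol and 565 by an older symbol. The name in the file was kept for the other 24300. This gave 22139 measured genes, 15588 of them with a current symbol. Probe coordinates are those of the array files on mouse build mm9. A genome sequence was not used here, so the place of a probe within exons was not determined.

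With 1 array per genotype no test was possible, and the number of arrays limits the precision. A fixed size rule of 2-fold (1 log2 unit) took the place of a test. Technical spot noise was estimated from the probes printed 10 times, as the SD between their spots at each level. For a difference between the arrays it came to 0.26 log2 units at a scaled level of -3, 0.08 at the median level of measured genes and 0.06 at a scaled level of 3. This covers printing, hybridisation and scanning within an array, and says nothing about animals or preparations. In 20 simulated pairs of arrays with 22139 genes, spot noise alone put a mean of 40.9 genes with no difference past 2-fold (range 30 to 48). Of the simulated genes set to differ by 1.5 log2 units, 98.8% passed the rule. The set of measured probes was kept fixed, so this share does not count genes that would fall below background on 1 array.

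A total of 31 gene lists with 619 members were fixed before the data were examined, and 552 members were measured. For each list, the median difference was set against 10000 random lists of the same size matched on mean level in 20 bins. Its percentile describes these 2 arrays only, and lists between the 2.5 and 97.5 percentiles are said to lie within the random range. Ccnb1, Asns, Loxl1 and Ddx3y were picked after their values had been seen, and Xist is named only because it did not count as measured. The other genes named in the results were also chosen by a fixed rule. They are Cth, Txnip, Ins1, Ins2 and Gcg, and the 12 highest and 12 lowest genes with a proper symbol and a mean level above the median of measured genes. In each list, up to 4 members with the largest absolute difference were added, plus up to 4 more where these reached 2-fold. The last part of the rule takes the 6 largest bounds on each side among genes above background on 1 array only. For such a gene, the normalized level on the bright array was set against the higher of the lowest well-above-background signal of the other array and the probe's own signal there, which gives "at least N-fold". Probes of a gene that disagreed in direction by 2-fold or more are reported as such. A few genes that the rule names are not reported here.

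Alternatives were scaling to the median, to the 75th percentile of detected probes, quantile and cyclic loess normalization, and centring on spike-in controls. Others were normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, no filter on dim probes, genes above the median level only, outlier spots kept, the mean of all probes of a gene, the authors' deposited table, and size rules of 1.5-fold and 3-fold. One alternative was added after the slide layout had been seen. It left out every probe with a spot in a local patch, defined as 4 or more other spots within 40 pixels (120 micrometres) that were at least 4-fold brighter on the same array. The spot's own value was not used in this definition. Patches held 3019 probes (5.42%) and the chosen probe of 1311 measured genes (5.92%). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1. The steps were tested on simulated data.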

Results

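Transcript levels were measured in beta cells from C57BL/6J mice aged 6 months on a high-fat diet, with 1 array for wild-type animals (CSE-WT, the control) and 1 for animals lacking the hydrogen sulfide-producing enzyme CSE (CSE-KO). The comparison asks which transcripts differ with the loss of CSE in beta cells under a high-fat diet. The labels call the samples beta cells, and whether the cells were sorted or taken as whole islets is not given in the sources used here. On the CSE-WT array the scaled levels were 9.92 for Ins1, 9.32 for Ins2, 9.52 for Gcg and 8.53 for the acinar gene Amy2a5. On the CSE-KO array they were 9.81, 9.26, 9.39 and 8.11. RNA of other pancreatic cells was thus abundant in both samples, and a difference below need not lie in beta cells. Because each genotype had 1 array, no difference below has a replicate check, and the values describe these 2 samples. On both arrays 22139 genes were measured.

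Cth, the gene of CSE itself, was not well above background on either array. Its 2 probes lie on the minus strand of chromosome 3 (mm9), at positions 157557667 to 157557726 and 157560183 to 157560242. Their intensities were 13.5 and 12.8 units on the CSE-WT array and 3.15 and 3.68 units on the CSE-KO array. The 95th percentile of 308 negative-control spots was 4.32 units on the CSE-WT array and 3.43 on the CSE-KO array. On the CSE-WT array 9 negative controls were as bright as either Cth probe. On the CSE-KO array 129 and 9 were. The Cth probes lay outside local patches of the slide, whereas 9 of the 10 negative controls above 10 units on the CSE-WT array lay in such patches. No fold is given, because both probes failed the detection rule in both samples. Where these probes lie relative to the deleted part of the gene is not known here, so they give no firm check of the genotype labels.

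Cell cycle genes were higher in the CSE-KO array. Of 23 measured members 20 were higher, 9 of them by at least 2-fold, and 17 by more than 3 times the spot SD, and 3 were lower. The proliferation marker Mki67 was 2.69-fold higher, the mitotic cyclins Ccnb2 and Ccna2 were 2.49-fold and 2.45-fold higher, and Birc5, a component of the chromosomal passenger complex, was 2.33-fold higher. Top2a (2.25-fold), the replication helicase subunit Mcm5 (2.24-fold), the mitotic kinase Plk1 (2.08-fold) and the cyclin Ccnb1 (2.04-fold) were also past 2-fold. The median of the list was 0.71 log2 units, above all 10000 random lists of matched level (random range -0.09 to 0.10). Cdk1 was 2.16-fold higher by its chosen probe, whereas its other probe, in a local patch of the slide described below, gave a difference of -2.32. Most of these transcripts were dim, and over the 7 members above the median level of measured genes the median was 0.12.

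Reg family genes, which encode secreted lectin-like proteins of the pancreas, were higher in the CSE-KO array in 4 of 4 measured members (median 0.81 log2 units, above all random lists). Reg3b was 3.06-fold, Reg2 1.85-fold, Reg3d 1.67-fold and Reg1 1.52-fold higher. Reg3g was above background on the CSE-KO array only, at least 6.80-fold higher. These genes are close relatives, and cross-hybridisation between them was not excluded.

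Interferon-response genes and macrophage markers were also higher in the CSE-KO array, while the median of the lymphocyte markers lay within the random range. Interferon-response genes were higher in 19 of 23 members (median 0.30, above all random lists), with 2 past 2-fold. These were the transcription factor Irf7 (2.18-fold) and the antiviral GTPase Mx1 (2.04-fold), followed by Ifit3 (1.87-fold) and Ifit2 (1.71-fold). Macrophage markers were higher in 18 of 22 members (median 0.32, above all random lists), including the integrin Itgax (1.86-fold), the Fc receptor subunit Fcer1g (1.54-fold) and the complement gene C1qc (1.46-fold), while the lysozyme gene Lyz1 was 1.60-fold lower. Inflammatory and NF-kB target genes were higher in 9 of 16 members (median 0.13, percentile 98.0). The chemokines Cxcl10 (2.59-fold) and Ccl5 (2.49-fold) were higher, and Il1b (-0.73 log2 units) and Socs3 (-0.63) were lower. The median of this list changed sign without a filter on dim probes (-0.12) and over members above the median level (-0.0047). Cxcl12 in this list differed by 0.36 by its chosen probe and by -2.08 by its other one. Lymphocyte markers had a median of 0.01 (percentile 51.2), with 7 of 12 higher. Of 20 listed, 12 were measured, and the standard error of the median over members was 0.17, against 0.097 for macrophage markers. Past 3 times the spot SD, 1 lymphocyte marker was higher and 0 were lower.

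**Figure D1:**
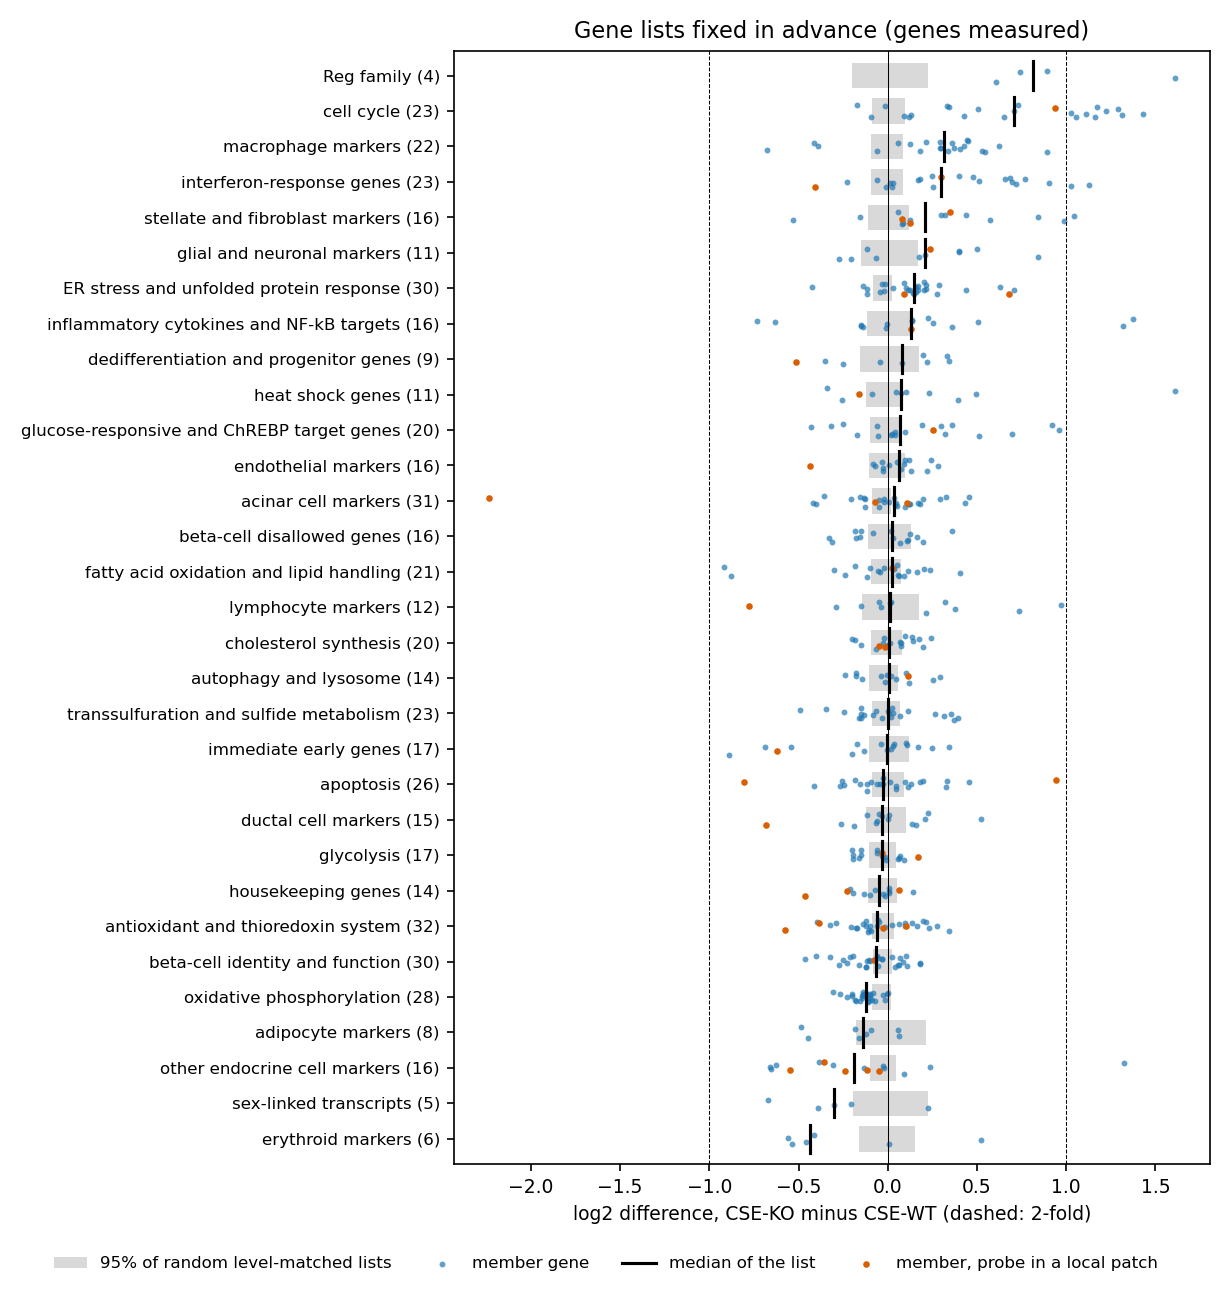
Log2 differences between the CSE-KO and CSE-WT arrays (x axis) for the measured members of 31 gene lists (rows, number measured in brackets). Points are genes, orange where the probe lay in a local patch of the slide, black bars are list medians and grey bands hold 95% of random level-matched lists. Cell cycle and Reg family genes have the highest medians (0.71 and 0.81) and erythroid markers the lowest (-0.44).

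Genes of the unfolded protein response, which is activated by misfolded protein in the endoplasmic reticulum, were higher in the CSE-KO array by small amounts. Of 30 members 22 were higher (median 0.15, above all random lists) and none reached 2-fold. Trib3, a pseudokinase induced by ATF4 and CHOP, was 1.63-fold higher, the glutathione-degrading enzyme Chac1 1.55-fold, and Edem1, which acts in degradation of misfolded glycoproteins, 1.35-fold. Derl3 was 1.60-fold higher, with its probe in a local patch bright on the CSE-WT array, which would lower its difference and not raise it. Asparagine synthetase (Asns) went the other way (-0.43). Apoptosis genes as a list did not stand apart (median -0.03, percentile 28.6, 12 of 26 higher). This sign turned when arrays were scaled to their medians, under normexp with quantile and over members above the median level. Within the apoptosis list Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was 1.92-fold higher and the death receptor gene Tnfrsf10b was 1.75-fold lower. Both probes lay in local patches bright on the CSE-WT array, which would lower a difference and not raise it. Pmaip1 (0.45) and Casp12 (-0.41) differed by less than 3 times the spot SD. Heat shock genes had a median of 0.08, at the 97.5 percentile of random lists and so on the edge of the random range, with the stress-induced chaperone Hspa1a 3.05-fold higher and 7 of 11 members higher.

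Txnip, which encodes the inhibitor of thioredoxin that is induced by glucose, was 1.95-fold higher in the CSE-KO array, with its 2 probes at 0.95 and 0.96 log2 units. Its probe lies on chromosome 3, positions 96365147 to 96365206 (mm9). Glucose-responsive and ChREBP target genes, the list that holds Txnip, were mixed. Of 20 members, Txnip included, 14 were higher (median 0.07, percentile 96.1), none past 2-fold, with Rgs16 at 1.89-fold and Klf10 at 1.43-fold. Antioxidant and thioredoxin system genes had a median of -0.06 (percentile 13.2), with 12 of 32 higher. The metallothioneins Mt1 (-0.39) and Mt2 (-0.39) and the peroxidase gene Gpx8 (-0.57) were lower, Mt2 and Gpx8 with probes in patches, and extracellular superoxide dismutase Sod3 was higher (0.34). Transsulfuration, methionine and sulfide genes had a median of 0.00 (percentile 64.3, 12 of 23 higher), whose sign depended on the processing. It turned under cyclic loess, spike-in scaling and both normexp settings. It also turned without a filter on dim probes, with the mean of probes and over members above the median level. Within this list Cbs, the other transsulfuration enzyme, was 1.31-fold higher, Gnmt was 1.29-fold higher, and Ahcy, which hydrolyses S-adenosylhomocysteine, was 1.41-fold lower. Bhmt (0.36) was within 1 spot SD of 0.

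Beta-cell identity genes differed little. No member of the 30 reached 2-fold, 10 were higher and 20 lower, and the median of -0.07 lay within the random range (percentile 8.85). By more than 3 times the spot SD, 1 member was higher and 8 were lower. Without patch probes the median was -0.08 (percentile 3.48), nearer the lower end of the random range. Ins1 (-0.12) and Ins2 (-0.06) were close to equal on the arrays. The Ins1 probe was the brightest gene probe on both arrays, so quantile scaling sets its difference to 0 by construction. In the authors' deposited table, whose sorted columns are nearly equal, it also came to 0. These 2 settings therefore do not test its sign. The sign of Ins2 did not hold under quantile or cyclic loess scaling or in the authors' table. The largest differences were in Nnat (-0.46), the transcription factor Isl1 (-0.40), the channel gene Trpm5 (-0.33) and Sytl4 (-0.27). Dedifferentiation and progenitor genes had a median of 0.08 (percentile 79.4), with Gast at 0.34, Aldh1a3 at 0.33, Hes1 at -0.35 and Neurog3, in a local patch, at -0.51. Genes normally kept silent in beta cells had a median of 0.02 (percentile 61.4), and 9 of 16 members were higher, with Cxcl12 at 0.36, Oat at 0.20, Smad3 at -0.33 and Maf, within 1 spot SD of 0, at -0.31.

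Oxidative phosphorylation genes were lower in the CSE-KO array in 27 of 28 members, each by a small amount. Their median was -0.12 (percentile 0.14), and Cox5a (-0.31), Ndufb5 (-0.27), Uqcrfs1 (-0.23) and Atp5pb (-0.20) differed most. The 3 probes of Ndufb5 ranged from -0.27 to 0.25. Of the 28 members 6 were lower by more than 3 times the spot SD. Over the scaling alternatives and the authors' table the median of the list lay between -0.14 and -0.07. Glycolysis genes (median -0.03, percentile 45.9) and cholesterol synthesis genes (0.01, percentile 60.5, sign turned by spike-in scaling) lay within the random range. Among fatty acid oxidation and lipid genes (median 0.02, percentile 78.9), the pyruvate dehydrogenase kinase Pdk4 was 1.89-fold lower, the coactivator Ppargc1a was lower by 0.88 log2 units (-0.88), and Acadm was higher (0.41). Autophagy and lysosome genes (0.00, percentile 78.2) and immediate early genes (-0.00, percentile 43.6) had medians at 0 whose signs depended on the scaling, with Egr1 1.85-fold lower and Nr4a1 at -0.69. Housekeeping genes had a median of -0.05 (percentile 32.7), which turned sign under quantile and cyclic loess scaling and in the authors' table.

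Most listed markers of other pancreatic cell types were above background on both arrays, and some differed between them. Acinar markers were measured for 31 of 33 members. Their median was 0.04 (percentile 99.5) while their mean was -0.05, because the probe of Ptf1a, in a local patch, gave -2.24. Ctrb1 (0.46) and Rbpjl (0.43) were higher and Amy2a5 (-0.42) was lower, a gene whose probes can also bind other amylase transcripts. Markers of other endocrine cells were lower in 13 of 16 members (median -0.19, below all random lists). This median came to -0.10 under quantile scaling, -0.11 under cyclic loess and in the authors' table, and -0.14 (percentile 1.58) over the 11 members outside patches. The alpha-cell regulators Irx1 (-0.66) and Irx2 (-0.62) were lower, the glucagon gene Gcg differed by -0.14 (-0.16 to -0.0063 over the scaling alternatives and the authors' table), and the ghrelin gene Ghrl was 2.51-fold higher. Stellate and fibroblast markers were higher in 14 of 16 (median 0.21, percentile 99.9), with Col3a1 2.06-fold, Dcn 1.98-fold and Col1a1 1.79-fold higher and Loxl1 1.45-fold lower. Glial and neuronal markers were higher in 7 of 11 (median 0.21, percentile 99.2), led by Prph (0.84), but had a median of -0.21 over members above the median level. Without patch probes their percentile was 97.5, just within the random range.

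Erythroid markers were lower in 4 of 6 members (median -0.44, below all random lists). They included the haem synthesis enzyme Alas2 (-0.56) and the haemoglobin genes Hbb-b2 (-0.54) and Hba-a1 (-0.46), whose probes can bind near-identical copies, while Car1 was higher (0.53). Endothelial (0.06, percentile 90.1), ductal (-0.03, percentile 32.3) and adipocyte markers (-0.14, percentile 5.49) lay within the random range. Sex-linked transcripts had a median of -0.30 (percentile 0.305). The Y-linked genes Ddx3y (-0.21), Eif2s3y (-0.39) and Uty (-0.67, its other probe at 0.04) were above background on both arrays. Xist was not well above background on both arrays, which leaves open detection on 1 of them. Of the 31 lists, 9 lay above the random range, 4 below and 18 within it, heat shock genes at its edge counted here, and without patch probes the numbers above and below were again 9 and 4, with glial markers no longer above the range and heat shock genes above it (percentile 98.5). Of the list members named, Ins1, Gcg, Pmaip1, Rbpjl, Loxl1, Car1, Cxcl12, Oat, Ifit2, Smad3, Gast, Hes1 and Ddx3y differed by 1 to 3 times the spot SD, and Ins2, Bhmt, Casp12 and Maf by less than 1. The SD between probes of a gene was larger, at 0.29 log2 units against a spot SD of 0.08 at the median level. A value past 3 times the spot SD may therefore still depend on the probe.

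Across all 22139 genes, 159 were at least 2-fold higher and 197 at least 2-fold lower in the CSE-KO array (1.61% together), and the levels correlated at r = 0.994 across genes, which are not independent replicates. Many of the lower genes lay in small bright patches on the CSE-WT array. Patches held 133 of the 197 lower genes and 7 of the 159 higher ones, and without patch probes 155 genes were higher and 65 lower. Of the 356 genes past 2-fold, 339 were at or below the median level, and 14 higher and 3 lower genes were above it. Among 71 such genes with 2 or more measured probes, all probes pointed in 1 direction for 36 and all passed 2-fold for 12.

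**Figure D2:**
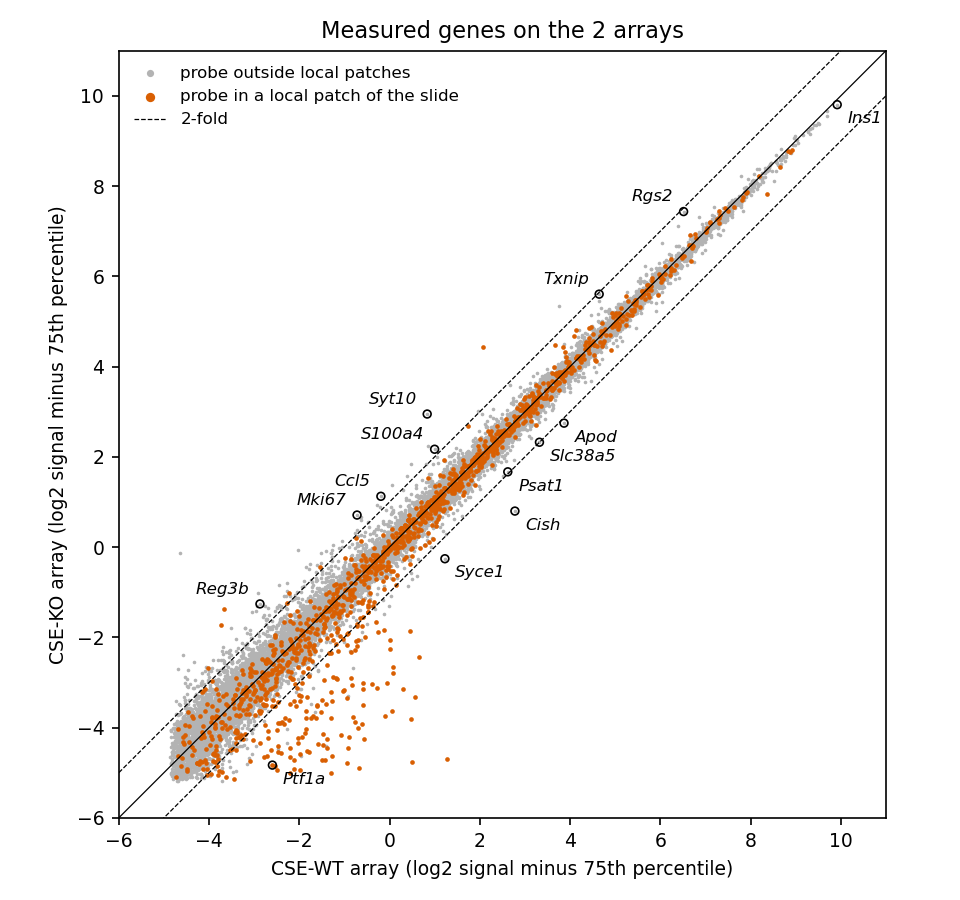
Normalized levels of the 22139 measured genes on the CSE-WT array (x axis) and the CSE-KO array (y axis), both as log2 intensity minus the 75th percentile. Each point is a gene, orange where its probe lay in a local patch, and dashed lines mark 2-fold. Most points far below the diagonal at low levels are orange, 133 of the 197 genes at least 2-fold lower.

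Among well-expressed genes, the highest in the CSE-KO array was Syt10, a synaptotagmin, at 4.33-fold. H19, an imprinted non-coding RNA, was 2.31-fold higher by its chosen probe, but its 4 probes ranged from -0.82 to 1.21. The calcium-binding protein genes S100a4 (2.25-fold) and S100a6 (1.93-fold) were higher, as were the microtubule regulator Stmn1 (2.07-fold), Dnm1 (1.96-fold, its other probe at 0.20) and the G-protein regulator Rgs2 (1.89-fold). The lowest was Cish, a feedback inhibitor of cytokine receptor signalling through STAT5, at 3.95-fold lower. Syce1, a meiotic synaptonemal complex gene, was 2.80-fold lower, the apolipoprotein gene Apod 2.17-fold and the amino acid transporter gene Slc38a5 2.00-fold. Genes of serine and mitochondrial folate metabolism followed, with Psat1 1.94-fold and Aldh1l2 1.93-fold lower. Mdm1 (1.89-fold), Cebpd (1.78-fold) and Sult1c2 (1.77-fold) were also lower. None of these genes outside the lists had its probe in a patch.

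Some transcripts were above background on 1 array only, 577 genes on the CSE-WT array and 1248 on the CSE-KO array. The floor was lower on the CSE-KO array, with a median negative control of 3.11 units against 3.86. The larger count there therefore need not mean more transcripts. On the CSE-WT array alone, 346 genes had a bound of at least 2-fold, and 280 of these lay in patches. The 6 largest bounds, Olfr1201 (at least 40.6-fold), Cd209c (at least 32.8-fold), Pcdh10 (at least 32.5-fold), Olfr1055 (at least 31.7-fold), Abcb5 (at least 30.9-fold) and Olfr118 (at least 28.9-fold), all came from patch probes. On the CSE-KO array alone 82 genes had such a bound, 8 of them in patches. Defa37 (at least 10.2-fold) and Zfp474 (at least 6.53-fold) were in patches, and Olfr916 (at least 9.64-fold), Adamts6 (at least 8.47-fold) and Galr2 (at least 6.98-fold) were not.

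**Figure D3:**
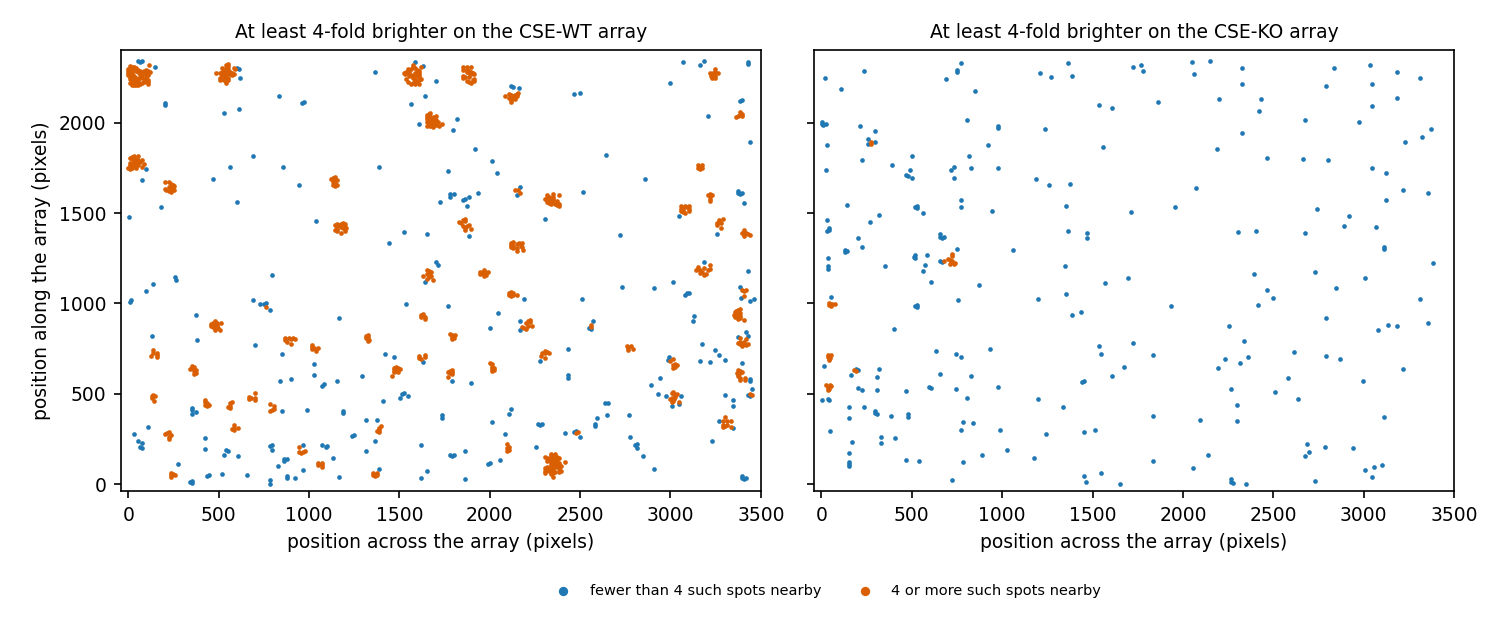
Positions on the array, in pixels, of spots at least 4-fold brighter on the CSE-WT array (left, 974 spots) or on the CSE-KO array (right, 301 spots). Orange spots had 4 or more other such spots within 40 pixels, which held for 71.8% on the left and 9.63% on the right.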

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

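The alternative without patch probes was chosen after the slide layout had been seen; the others were planned. No paired analysis was possible because each genotype had 1 array. Cth has no value here, since neither probe was well above background on either array. Over the scaling alternatives, the authors' table, outlier spots kept and the mean of probes, the counts lay within 1.5 times the 159 higher and 197 lower genes. Counts for higher and lower genes were 38 and 96 under normexp with quantile, 36 and 97 under normexp with 75th percentile scaling (the added offset shrinks dim differences by construction), 1128 and 1436 with no filter on dim probes, 14 and 3 above the median level, 684 and 553 at 1.5-fold, and 19 and 99 at 3-fold, 87 of these 99 in patches. Without patch probes 65 genes were lower, 64 of them shared with the 197. The median of beta-cell identity genes was -0.0030 under normexp with quantile, -0.11 with the mean of probes and -0.030 in the authors' table. Antioxidant genes came to -0.010 under normexp with quantile and -0.0067 with the mean of probes. Above the median level, transsulfuration genes came to -0.059, cell cycle genes to 0.12, glial markers to -0.21 and inflammatory genes to -0.0047, and without a filter inflammatory genes came to -0.12, each over a different set of members. Cdk1 came to -0.61 with the mean of probes, because its other probe, in a patch, read -2.32. In the other cases the cause was not tested. Of 403 list medians over all alternatives 33, from 12 lists, had the other sign, 3 of them from lists outside the random range. Apart from these 3, 380 moved by less than their standard error and 20 by more. Of 1848 values of named genes 10, from 5 genes, had the other sign or came to 0, with Cdk1 the 1 gene past 2-fold among them. Apart from Cdk1 with the mean of probes, 1802 moved by less than the SD between probes of a gene, 0.29, and 45 by more. Signal over background limits dim genes most, where spot noise is largest.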

Other observations

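The tests chosen only after the result was seen are those of scaling, spot noise, animals, local deposits and collection time, and the gene groups in the next 2 paragraphs; the macrophage test was set before its value was seen, and the test on other probes was limited to detected probes after its value over all of them had been seen.

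Serine and one-carbon synthesis genes, grouped after Psat1 and Aldh1l2 had been seen among the lowest genes, were lower in the CSE-KO array in 9 of 11 members (median -0.20, percentile 0.10 among random level-matched lists), these 2 included. Without them 7 of 9 were lower (median -0.19, percentile 0.455). Phgdh, the entry enzyme of serine synthesis, differed by -0.50, Psph by -0.46 and the mitochondrial Shmt2 by -0.53. Pycr1 (0.20), a proline synthesis gene that the group also held, was higher, and Aldh1l1 (0.15) was within 1 spot SD of 0. Several of these genes, like Asns (-0.43), are known targets of ATF4, yet the ATF4 targets Trib3 (0.71) and Chac1 (0.63) were higher. Around Cish (-1.98), other feedback genes of JAK-STAT signalling, grouped after that value had been seen, had Socs3 at -0.63, Socs2 at -0.60 and Bcl6 at -0.26, with Socs1 (0.35) and Pim1 (0.48) higher. The median of these 5 was -0.26 (percentile 0.90), over members that differed in both directions.

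Within the cell cycle list, mitosis and spindle genes were higher in 11 of 11 members with a median of 1.11, and DNA replication genes in 6 of 7 with a median of 0.34. The collagens of the fibroblast list had a median of 0.64 (4 of 4 higher).

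The higher cell cycle genes in the CSE-KO array were not accounted for by scaling, which moves genes of the same level alike, since the list lay at percentile 100 among random lists of matched level. Under the 5 settings that are not 1 shift for all genes its median was 0.63 to 0.71. Nor did spot noise account for them, since 17 members were higher by more than 3 times the spot SD. A larger share of macrophages that cycle at an unchanged rate would lift macrophage markers at least as much. Their median lay 0.39 log2 units below that of the cell cycle list. The combined standard error of 0.16 is a spread over list members, not over animals. Over members above the median level the order was the reverse, with 0.36 for macrophage markers and 0.12 for 7 cell cycle genes. The comparison therefore does not decide on that account. A higher cycling rate in some immune, stromal or endocrine cell also stays open. Differences between animals or preparations cannot be told apart from genotype with 1 array per genotype. Without patch probes the list kept a median of 0.68 over 22 members.

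The dim transcripts that were bright on the CSE-WT array alone are consistent with local deposits or damage on that array. Of the 974 spots at least 4-fold brighter there, 71.8% lay beside 4 or more others, against at most 0.821% in 100 random draws of dim spots. Of the 301 spots brighter on the CSE-KO array 9.63% did so, against at most 0.332% in random draws. Some patches thus lay on that array too. Negative-control probes, which match no transcript, behaved alike: 10 exceeded 10 units on the CSE-WT array, 9 of them in patches, with a maximum of 158 units, against 3 and 37.1 units on the CSE-KO array. Transcripts present in the wild-type sample alone would also light up other probes of the same genes. The 947 other probes outside patches had a median difference of -0.19, with 3.80% at least 2-fold lower. Of these, 311 from 192 genes were well above background on the CSE-WT array, and 302 from 187 genes on both arrays. The median of the 311 was 0.010 with 1.29% at least 2-fold lower, against -0.0027 and 1.05% for such probes of other genes. This argues against that account for these 192 genes. Genes with a probe above background on both arrays were not counted among the 577 on the CSE-WT array alone. The test therefore says little about those 577. The remaining 636 of the 947 probes had a median of -0.32 with 5.03% at least 2-fold lower. Probes of other genes near the floor gave -0.32 and 5.57%, so these 636 decide nothing.

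Among clock genes, Arntl (0.90) and Nfil3 (0.77) were higher and Dbp (-0.72), Per2 (-0.42), Tef (-0.40) and Nr1d2 (-0.37) lower in the CSE-KO array, while Per1 (0.23) of the Dbp phase was higher, and Hlf (0.11) and Nr1d1 (-0.04) were within 1 spot SD of 0. The other measured Arntl-phase genes, Clock (0.04) and Cry1 (0.17), were within 1 spot SD of 0, so the values of that phase rest on 2 genes of a list made after they had been seen. The Arntl-phase list lay at percentile 99.9 of random lists, and the Dbp-phase list lay within its random range (percentile 12.7). The median of the Arntl-phase genes (0.47) minus that of the Dbp-phase genes (-0.09, 6 of 9 lower) was 0.56, at percentile 99.9 of random pairs of lists (random range -0.26 to 0.28). Collection of the samples at different times of day may account for this. No hour of collection is given in the sources used here, so it cannot be told apart from an effect of genotype on the clock.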
